A study of Heliothis virescens with 16 samples.

How the data were processed

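The series measured Cy3-labelled RNA of 5 pooled larvae per sample on 16 one-colour arrays, 4 for each of 4 groups of tissue and diet. Groups and replicate numbers were taken from the sample labels, which name 4 biological replicates per group. Per the labels' protocols, spike-in RNA was added to total RNA before labelling and amplification. The scanner intensity values (processed signal, median spot signal and median local background) were made with Agilent Feature Extraction 10.7.3.1, per the file headers, which also record background subtraction and detrending in the processed signal. The submitters' processing notes name version 9.1. The deposited intensity files hold 172562 spots that are not controls and 4854 control spots per array.

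The deposited value table holds log2 values. Its scale, centring and direction are not given in the sources used here and were settled from the values. A recomputation from the processed signal (log2, mean over spots of a probe, quantile normalization within the 8 arrays of a tissue, each probe centred on its median over those arrays) correlated with every column at r of at least 0.99995. Column medians lay between −0.00856 and 0.00587. The table was therefore used as an alternative only within a tissue.

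From the files, log2 of the processed signal was taken and each array's 75th percentile subtracted, so that a relative log2 signal of 0 is that percentile. Spots flagged as outliers or by hand (2875 over all arrays) were left out, and spots of one probe were averaged. Of 167720 probes, the one with the highest mean over the 16 arrays stood for each of 80237 contigs, 62542 of which had more than 1 probe. The contig names fall into 4 series of 34352, 24372, 19214 and 2299 names. Each series was also counted alone, since assemblies can hold 1 transcript more than once.

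A contig entered a comparison when its probe was well above background on at least 4 of the arrays compared. One linear model with 4 group means was fitted over all 16 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 12 residual degrees of freedom). P-values were adjusted by Benjamini-Hochberg within a comparison, with a threshold of 0.05. Fold changes are 2 to the power of the log2 difference. A contig with no probe well above background on any array of a group has only a bound there. It is the mean of the bright group against the mean, over the dim group's arrays, of the higher of its own signal and the lowest signal well above background. Such a bound is written as at least N-fold. The adjusted p of such a contig tests the measured difference and not the bound. Values with n = 4 for a whole array were compared by exact permutation.

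The groups, tests, naming rule and most alternatives were fixed before the data were examined. The named contigs were chosen by a rule that allowed at most 2 per direction and comparison where no gene has a name, taken here as those with the largest differences past the threshold whose groups do not overlap. Since values at the background have no order, a condition was added after the data were seen: only contigs well above background on all arrays compared were ranked, and HVI-Contig13333 in the gut is given as a bound beside this. For the difference between tissues all 16 arrays had to measure the contig, and the condition on overlap was not applied. By the gut minus body difference of each pool, 3 of the 4 contigs named there had diets that did not overlap, and HVI-RE-Contig_13999 did overlap. Gene lists and cell type markers set beforehand could not be matched, because the files name contigs and not genes and no annotation was used here, so no list was tested. Mean spot signals were not used here, so the normexp correction planned on them was run on the median spot signals, with an offset of 50.

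Residuals from the group means showed which arrays belong together. Gut and body arrays with the same number within a diet correlated at r between 0.209 and 0.424 over 58368 contigs (8 pairs, median 0.363), and all 8 gut arrays correlated best with the body array of their own number. Same-numbered arrays of different diets in one tissue had a median r of 0.0129. The numbers were therefore taken to pair gut and body within a diet and not the diets. This pairing comes from the data, while the labels say only that larvae were divided into both tissues and pooled. Each of the 4 slides held 1 group, and the 2 scan days held 1 tissue each, so slide could not be fitted as a block.

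The spread between pools was taken off the contigs' differences by subtracting, from the variance of the difference over contigs, the mean variance that the pools of both groups give a difference of 2 means. Chance overlap of the responses in gut and body was simulated with unchanged groups and a pool correlation of 0.363. The calling was tested on simulated data with 58395 contigs. In the gut comparison it recovered 37% of 100 contigs changed 2-fold and 82% of 100 changed 4-fold, with 8 false calls. In the rest of body comparison it recovered 41% and 89%, with 12 false calls. Far larger shares of contigs were called in the data, which makes the Benjamini-Hochberg threshold less strict there. Neither the recovery nor the number of false calls therefore carries over to the data. Alternatives covered the normalization, background correction, spike-in scaling (7 spike-in probes above background on all arrays), the filter on dim probes, the choice of probe, the variance model, thresholds, replicate and pool blocks, and leaving out arrays.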

Results

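RNA from the larvae of Heliothis virescens, the tobacco budworm, was measured on 16 one-colour Agilent arrays. Caterpillars that had newly moulted to the fifth instar fed for 3 days on bean-based artificial diet with 0.32% (w/v) gossypol or with none. Gossypol is a toxic polyphenolic aldehyde that cotton plants make. Each larva was then divided into the gut and the rest of the body, and tissue of 5 larvae was pooled into one sample. The 4 groups were gut on control diet, gut on gossypol diet, rest of body on control diet and rest of body on gossypol diet, with 4 pools in each. The array carried probes for 80237 assembled transcript sequences, called contigs here. The files pair no contig with a gene, so contigs are given by the names on the array, and 1 transcript can appear under several contig names.

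On the control diet 49733 ± 2543 contigs (SD, n = 4) were well above background in the gut and 50648 ± 2110 in the rest of the body. On the gossypol diet the numbers were 53268 ± 999 and 54266 ± 1662. The difference between diets gave p = 0.114 in the gut and p = 0.0571 in the rest of the body (two-sided exact permutation tests, n = 4 against 4, where the smallest possible p is 0.0286). The 75th percentile of the signal, to which each array was scaled, averaged 103 ± 15.1 in control guts, 135 ± 10.6 in gossypol guts, 116 ± 23.0 in control bodies and 141 ± 23.9 in gossypol bodies. Arrays of one group correlated across contigs at a median r between 0.964 and 0.975, gut arrays of different diets at 0.923 and body arrays of different diets at 0.937. Gut and body arrays of the control diet correlated at a median r of 0.762. Contigs are not independent replicates, so these coefficients describe the arrays only. The number of arrays limits the precision of every value that follows.

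The first comparison asked which transcripts change in the gut of larvae fed gossypol. Of 52286 contigs tested, 24760 (47.4%) differed from the control gut, 13532 higher and 11228 lower (limma, Benjamini-Hochberg adjusted p under 0.05). At least 2-fold differences were called for 7404 higher and 6563 lower contigs. At least 16-fold differences were more frequent among the falls, with 228 lower and 80 higher contigs. HVI-RE-Contig_10636 and HVI-Contig3376 rose most among contigs measured on every gut array. HVI-RE-Contig_10636 rose from a relative log2 signal of 0.32 ± 1.62 to 8.02 ± 1.42 (SD, n = 4), a 208-fold rise (log2 difference 7.70 ± 0.90 SE, adjusted p = 1.43e-05). HVI-Contig3376 rose from 0.54 ± 1.24 to 8.17 ± 0.94, a 198-fold rise (7.63 ± 0.66 SE, adjusted p = 1.58e-06); its other probe gave a log2 difference of 2.55 and the mean of its probes 5.09. Among the same contigs, HVI-RE-Contig_1304 and HVI-Contig21425 fell most. HVI-RE-Contig_1304 went from 8.15 ± 1.52 to 1.28 ± 1.59, a 117-fold fall (−6.87 ± 1.10 SE, adjusted p = 1.79e-04), and HVI-Contig21425 from 8.18 ± 1.47 to 1.33 ± 1.68, a 115-fold fall (−6.84 ± 1.11 SE, adjusted p = 1.98e-04), with −5.09 for its other probe and −5.96 for the mean of its probes. Without single arrays HVI-RE-Contig_10636 moved to 7.09 (control gut 1), 8.34 (control gut 2) and 8.33 (gossypol gut 3). Without control gut 3 HVI-RE-Contig_1304 and HVI-Contig21425 were at −7.56 and −7.52, and without gossypol gut 2 at −6.17 and −6.11. With arrays scaled to the spike-in probes, 18949 contigs differed, 11785 higher and 7164 lower, and the median of all contigs moved from 0.08 to 0.19. The balance turned with the mean of all probes (10712 higher, 11175 lower) and with no filter on dim probes (13837 higher, 14235 lower). Rises outnumbered falls in the other alternatives.

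**Figure D1:**
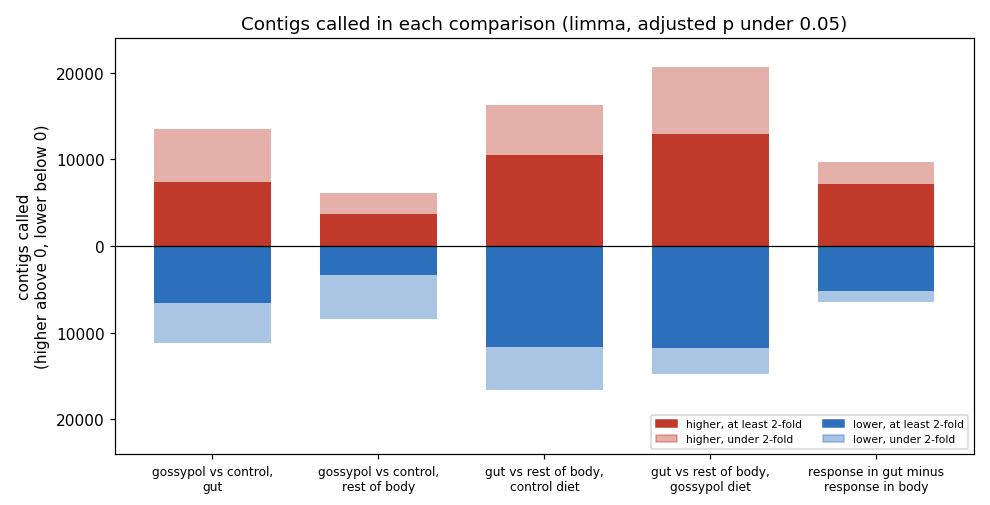
Number of contigs called in each of 5 comparisons (limma, adjusted p under 0.05), with higher contigs drawn above 0 and lower contigs below, and the dark part of each bar for differences of at least 2-fold. For the gut on gossypol against control diet the bar reaches 13532 higher and 11228 lower contigs, and for the rest of the body 6094 and 8444, on arrays scaled to their 75th percentile.

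A set of 1073 contigs was well above background on all 4 gossypol gut arrays and, with none of their probes, on any control gut array, and 887 of these passed the test. The reverse held for 172 contigs, of which 165 passed. Against the lowest signal that counts as well above background, 10 of the 1073 were at least 10-fold higher and 14 of the 172 at least 10-fold lower with gossypol. The median bound was 1.47-fold for the 1073 and 3.59-fold for the 172. Detection was judged on the signal before scaling, and its 75th percentile averaged 135 on gossypol and 103 on control guts. The 2 counts are therefore no measure of contigs turned on or off. HVI-Contig13333 was measured on all 4 control gut arrays and on no gossypol gut array, a fall of at least 301-fold. Its limma adjusted p of 2.56e-06 belongs to the measured difference of −10.19, which includes signals at background, and does not test the bound. The bound was 189-fold without control gut 4 and 640-fold without control gut 3. In 42.7% of the contigs tested, the 4 gossypol guts lay entirely above or entirely below the 4 control guts, against 2.86% for random groups of this size. Of 11245 further measured probes of called contigs, 89.2% changed in the direction of the probe tested and 3.98% passed the test in the opposite direction. The 2 diets lay on separate slides, so slide and diet cannot be told apart by the design. Over 7 spike-in probes the gossypol minus control difference had an SD of 0.107 in the gut and 0.0376 in the body, against 1.03 and 0.813 for contigs of the same brightness after the spread between pools was taken off.

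The second comparison asked the same of the rest of the body, which holds all other tissues of the larva. Of 53068 contigs tested, 14538 (27.4%) differed between the diets, 6094 higher and 8444 lower with gossypol. At least 2-fold differences were called for 3693 higher and 3380 lower contigs. The called rises were larger than the falls, with a median of 2.27-fold against 1.83-fold, and 229 contigs rose but 60 fell at least 16-fold. Among contigs measured on every body array HVI-Contig3376 also led the rises, from 0.78 ± 1.06 to 8.78 ± 0.75 (SD, n = 4), a 256-fold rise (8.00 ± 0.66 SE, adjusted p = 2.09e-06), with 2.43 for its other probe and 5.22 for the mean of its probes. HVI-Contig19119 rose 253-fold, from 1.09 ± 1.01 to 9.07 ± 0.69 (7.98 ± 0.65 SE, adjusted p = 1.89e-06). HVI-Contig13333 fell 454-fold, from 8.37 ± 1.52 to −0.45 ± 0.64 (−8.83 ± 0.95 SE, adjusted p = 1.96e-05), or by 9.58 on the log2 scale without control body 3. HVI-Contig11199 fell 31.7-fold, from 2.05 ± 1.19 to −2.93 ± 0.21 (−4.99 ± 0.52 SE, adjusted p = 1.56e-05), but 1 of its 3 other probes gave a log2 difference of 0.19. Its difference was −2.53 for the mean of its probes and −2.76 with normexp background correction.

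**Figure D2:**
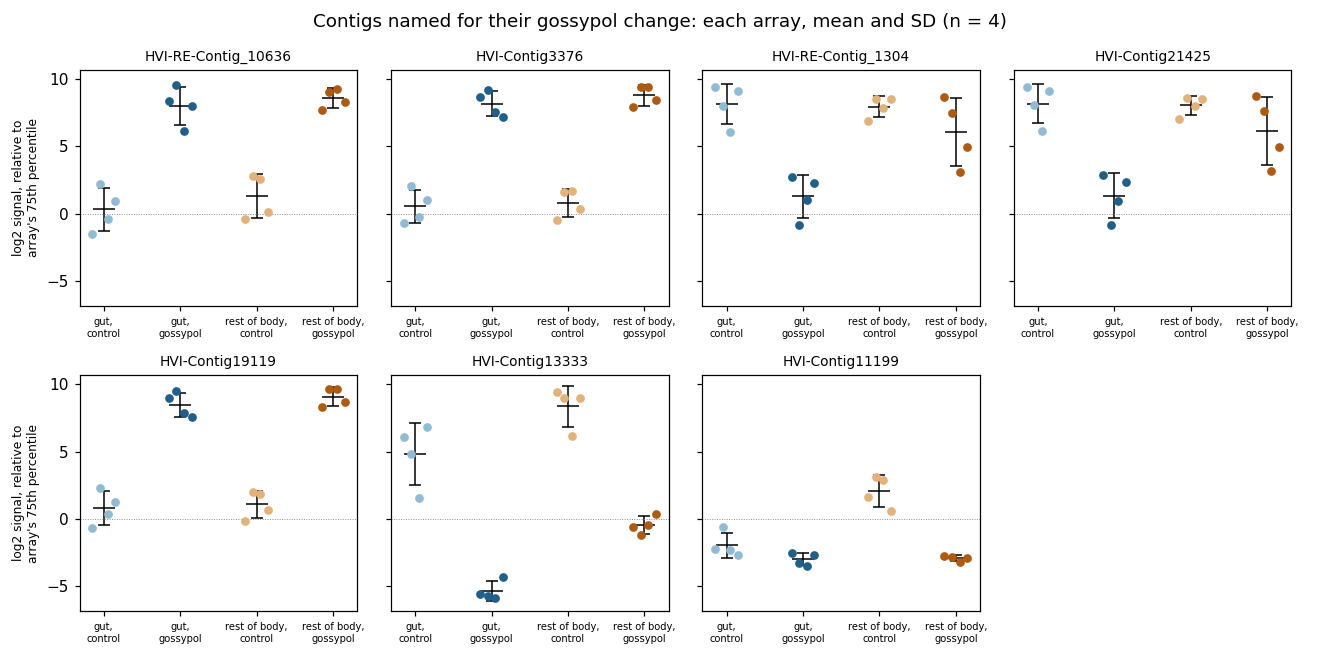
Relative log2 signal (y axis, 0 is the array's 75th percentile) of 7 contigs named for their gossypol change, with each array as a point and the mean and SD of 4 arrays per group as bars. HVI-Contig3376, HVI-Contig19119 and HVI-RE-Contig_10636 are higher on all gossypol arrays of both tissues, HVI-RE-Contig_1304 and HVI-Contig21425 are lower in the gut, and HVI-Contig13333 is lower in both tissues.

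In the rest of the body, 945 contigs were well above background on all gossypol arrays and no control array, with 720 past the test, and 92 the other way around, with 80 past the test. At least 10-fold bounds were reached by 44 and 5 of these, and the median bounds were 1.54-fold and 2.49-fold. Here too detection was judged before scaling, with a mean 75th percentile of 141 on gossypol and 116 on control bodies. The balance of rises and falls depended on the scaling. The spike-in signal relative to the 75th percentile was 4.18 ± 0.27 on control and 3.59 ± 0.31 on gossypol body arrays (log2, SD; p = 0.0571, two-sided exact permutation test, n = 4 against 4). With arrays scaled to the spike-in probes, 14110 contigs were higher and 1079 lower, and the median of all contigs moved from −0.08 to 0.51. The array of gossypol pool 4 carried more signal of gut contigs than the other 3 gossypol bodies. Gut contigs, at least 64-fold higher in gut than in body, were chosen on 2 control pools and followed in the body against the other 2, so that the choice did not set the change. Of 365 tested contigs chosen on pools 1 and 2, 49 rose and 7 fell with gossypol (13.4% and 1.92%, median change 0.86), against 7.27% higher and 9.20% lower among all other contigs. Without the array of pool 4, 54 rose and 10 fell among 357 (15.1% and 2.80%, median 0.23), against 5.18% and 6.75% of the others (median −0.09). Of 383 chosen on pools 3 and 4, 54 rose and 3 fell (median 1.04), against 8.46% and 9.08% of the others. Without that array 44 rose and 4 fell among 373 (11.8% and 1.07%, median 0.41), against 6.07% and 6.55% of the others.

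Both responses were then set side by side over the 48011 contigs tested in both tissues. A total of 7396 passed in both, 5793 in the same direction and 1603 in opposite directions. For all 1603 the test of the difference between tissues was passed too. Calls in opposite directions lead to this by themselves in a model with a shared spread, so it adds no support. Both tissues rose in 2356 contigs, where independent lists of these sizes would share 1313, and both fell in 3437, where they would share 1761. With spike-in scaling the same directions held 4219 and 401 contigs. At least 2-fold changes were shared by 1020 rises and 1298 falls, against 241 opposite changes. HVI-RE-Contig_10636, 208-fold higher in the gut, was 159-fold higher in the rest of the body (adjusted p = 6.42e-05), and HVI-Contig19119, 253-fold higher in the rest of the body, was 198-fold higher in the gut (adjusted p = 1.45e-06). At least 16-fold, 34 contigs rose and 13 fell in both tissues.

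**Figure D3:**
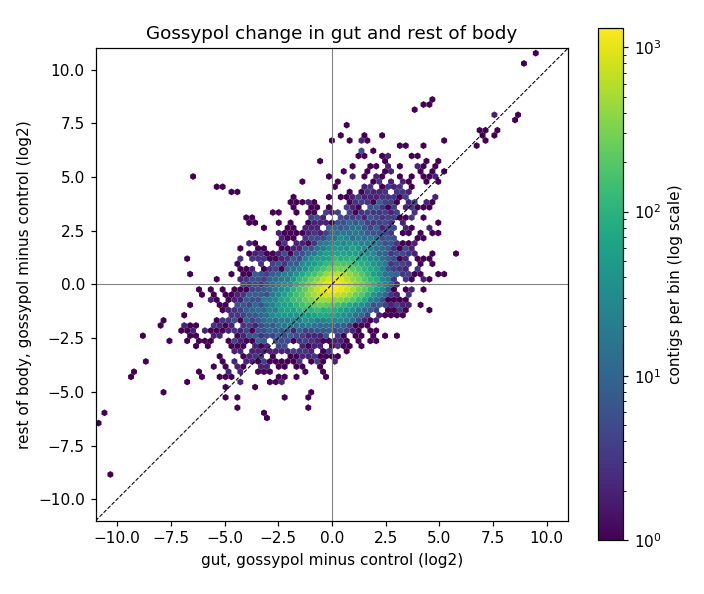
Log2 difference between gossypol and control diet in the gut (x axis) and in the rest of the body (y axis) for the 48011 contigs tested in both, with colour giving contigs per bin on a log scale and a dashed line of equal change. The cloud slopes upward (Pearson r 0.422), with a small set of contigs near 7 to 8 on both axes. For contigs not above background in one group the size of the difference is uncertain.

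The changes in the 2 tissues correlated across contigs (Pearson r 0.422, Spearman rho 0.340, covariance 0.382). Because gut and body samples of one number deviated together within a diet, 20 simulated data sets of unchanged groups with shared pools were drawn. These gave a mean r of 0.361, which returns the pool correlation of 0.363 put into the draws and is no separate measure of chance. The mean covariance was 0.0408. No draw called more than 1 contig in a tissue, so the draws say nothing about the number of shared calls. When the gut change was taken from pools 1 and 2 and the body change from pools 3 and 4, r was 0.337 and the covariance 0.358. With the pools exchanged, r was 0.297 and the covariance 0.302. When both changes came from pools 1 and 2, r was 0.405 and the covariance 0.442. With both from pools 3 and 4 these were 0.432 and 0.427.

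Whether the response differed between tissues was tested as the gut change minus the body change. Of 58395 contigs, 16231 differed, 9727 with the higher and 6504 with the lower value in the gut. Among the 13972 of these that were tested in both tissues, the change was larger in size in the gut for 10033 and in the body for 3939. HVI_Comb-contig69021 rose 5.51-fold in the gut (adjusted p = 0.00819) and fell 5.78-fold in the body (adjusted p = 0.0130), a difference of 4.99 ± 0.96 SE (adjusted p = 0.00168); its other probe gave 0.52 and the mean of its probes 2.76. HVI-Contig18935 rose 37.0-fold in the gut (adjusted p = 1.13e-06), while its body values were 1.10 ± 0.64 and 1.54 ± 0.44, a difference between tissues of 4.77 ± 0.60 SE (adjusted p = 9.85e-05). HVI-RE-Contig_24762 fell 41.9-fold in the gut (adjusted p = 7.89e-04) and rose 25.1-fold in the body (adjusted p = 0.00487), a difference of −10.03 ± 1.48 SE (adjusted p = 2.90e-04). Without control gut 3, control body 1 or control body 3 its difference was −11.14, −10.66 or −9.24, and without gossypol gut 3 that of HVI_Comb-contig69021 was 5.66. With normexp background correction HVI_Comb-contig69021 was at 3.77, HVI-Contig18935 at 3.75 and HVI-RE-Contig_24762 at −9.37.

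HVI-RE-Contig_13999 had the next lowest value among contigs measured on all 16 arrays, −6.12 ± 1.96 SE (adjusted p = 0.0313). Neither tissue passed the test alone (limma, adjusted p = 0.104 in the gut and 0.0962 in the body). The control gut spread was 4.27 SD around 4.05, and the model shares 1 spread over all 4 groups. In the body the contig rose 9.56-fold, from −1.17 ± 0.12 to 2.09 ± 0.51 (SD, n = 4), and the diets did not overlap there. In the gut minus body difference the diets overlapped, with −1.17 in control pool 3 and −1.56 to −0.30 in the gossypol pools. Its call ended without control gut array 1, 2 or 4, without gossypol gut array 2 or 4, without control body array 2 and without gossypol body array 3 or 4, where the adjusted p lay between 0.0508 and 0.0612. Without both arrays of control pool 1 the adjusted p was 0.0800. Without control gut array 3, on which this contig was at −2.30, the difference was −8.23 (adjusted p = 4.70e-07), and for the mean of its probes it was −3.76 (adjusted p = 0.0345). The gut falls of HVI-RE-Contig_1304 and HVI-Contig21425 also differed from their body changes, by −4.99 (adjusted p = 0.0278) and −4.93 (adjusted p = 0.0309). These body changes were −1.88 and −1.92 (limma, adjusted p = 0.228 and 0.223), with gossypol body SDs of 2.51 and 2.54. HVI-RE-Contig_1304 was at 3.11 and 4.91 on gossypol bodies 3 and 4 and at 8.67 and 7.51 on gossypol bodies 1 and 2. Control bodies ran from 6.85 to 8.52, so the fall is not shown to be confined to the gut. With spike-in scaling the count for the difference between tissues was 10637, with 2189 higher and 8448 lower in the gut, and the median of all contigs moved from 0.06 to −0.43.

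The tissues themselves were compared within each diet. On the control diet 32884 of 52134 contigs (63.1%) differed between gut and rest of body, 16300 higher in the gut and 16584 higher in the body. At least 16-fold differences were found for 1871 contigs higher in the gut and 1995 higher in the body. Among contigs measured on every array of both tissues, HVI-Contig18598 and HVI_Comb-contig76256 had the highest gut signal relative to the body. HVI-Contig18598 was at 9.49 ± 0.89 in the gut and −0.64 ± 1.90 in the body (SD, n = 4), 1118-fold apart (10.13 ± 0.84 SE, adjusted p = 8.26e-08). HVI_Comb-contig76256 was 1071-fold higher in the gut (10.07 ± 0.70 SE, adjusted p = 1.46e-08). Among the same contigs, HVI-Contig24127 and HVI-RE-Contig_443 were highest in the body relative to the gut, by 775-fold (−9.60 ± 0.82 SE, adjusted p = 1.24e-07) and 750-fold (−9.55 ± 0.79 SE, adjusted p = 8.81e-08), with −4.12 for the other probe of HVI-Contig24127 and −6.86 for the mean of its probes. Their control gut SDs were 2.50 and 2.40. Without control gut 2 they were at −10.65 and −10.56, without control gut 1 at −8.90 and −8.91, and without control gut 3 at −8.96 and −8.90. HVI-Contig18598 moved to 9.38 without control body 1 and 10.93 without control body 2, and HVI_Comb-contig76256 to 9.39 without control body 1. None of the 4 contigs passed the test for gossypol in either tissue.

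Contigs well above background on all 4 control guts and no control body numbered 1466, of which 435 were at least 10-fold higher in the gut, and 1674 held the reverse, of which 256 were at least 10-fold higher in the body. Gut arrays were scanned on one day and body arrays on another, so tissue and scan day cannot be told apart by the design. The SD of the gut minus body difference over the spike-in probes was 0.190 on the control diet, against 2.16 for contigs of the same brightness after the spread between pools was taken off.

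On the gossypol diet 35405 of 56086 contigs (63.1%) differed between the tissues, 20633 higher in the gut and 14772 higher in the body. With spike-in scaling the split was 9827 and 19426, and the median of all contigs moved from 0.20 to −0.32. HVI-Contig11010 was 1077-fold higher in the gut (10.07 ± 0.60 SE, adjusted p = 2.84e-09). On the control diet no body array measured it, and it was at least 1415-fold higher in the gut, or at least 2417-fold without control gut 1. Its limma adjusted p there, 7.51e-10, belongs to the measured difference of 12.05 and does not test the bound. HVI-Contig15846, at 8.53 ± 0.75 in the gut and −1.47 ± 0.51 in the body (SD, n = 4), was 1025-fold higher in the gut (adjusted p = 1.80e-06). HVI-Contig137 was 1257-fold higher in the body (−10.30 ± 0.38 SE, adjusted p = 4.57e-11), with −8.35 for its other probe and −9.32 for the mean of its probes, and fell 10.8-fold in the gut with gossypol (adjusted p = 8.38e-06). HVI-Contig5103 was 1160-fold higher in the body (−10.18 ± 0.41 SE, adjusted p = 1.09e-10) and rose 111-fold there with gossypol (adjusted p = 1.06e-07), but only 1 of its 3 other probes had the same direction between tissues, and the mean of its probes gave −5.11.

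Contigs measured on all gossypol guts and no gossypol body numbered 1459, with 250 at least 10-fold higher in the gut. The reverse held for 2728, with 804 at least 10-fold higher in the body.

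**Figure D4:**
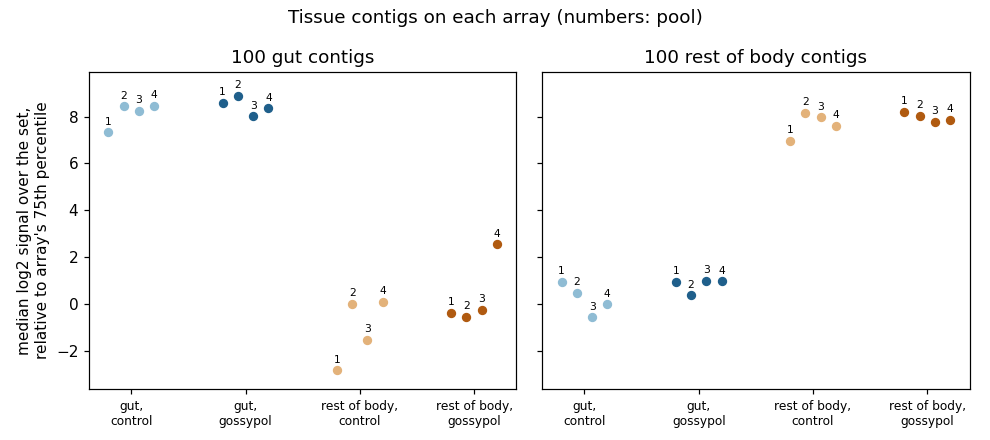
Median relative log2 signal over 100 abundant gut contigs (left) and 100 abundant rest of body contigs (right) on each of the 16 arrays, with pool numbers beside the points; each diet's arrays show the set taken from the other diet, so levels compare within a diet only. For gut contigs the rest of body array of gossypol pool 4 lies at 2.56 and the other 3 between −0.54 and −0.23, and control pool 1 is lowest of its group in both tissues.

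For each diet, 100 gut contigs and 100 body contigs with the largest tissue difference among the 2000 brightest were taken from the arrays of the other diet, so the sets differ between diets. On the control diet the gut contigs had a median of 8.11 ± 0.53 in guts and −1.04 ± 1.39 in bodies, and the body contigs 0.23 ± 0.65 in guts and 7.68 ± 0.52 in bodies (SD, n = 4). On the gossypol diet the gut contigs were at 8.45 ± 0.37 in guts and 0.36 ± 1.47 in bodies, and the body contigs at 0.84 ± 0.30 and 7.97 ± 0.19.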

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

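The tests of slide effects, of diet and scaling for pool 4 and of the shared pool deviations were chosen after the values were seen; the counts over other splits and the carry-over test were set beforehand. Single arrays far from the other 3 of their group appeared in 8 of 100 groups of 4 values, where chance gives about 1 in 20.

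The first pattern is the size of the gossypol response. Chance is argued against, since the real split alone (1 of 35) reached 24760 contigs in the gut and 14538 in the body. It cannot be excluded with 35 splits. At most 5 and 19 contigs were called in any other split, but these counts are no measure of chance calls. Mixing the diets adds their difference to the spread and so lowers the counts. Labelling, hybridisation or scanning that differed between slides and acted on spike-ins and contigs alike is argued against as the whole cause: the SD of the gossypol difference over 7 spike-in probes was 0.107 in the gut and 0.0376 in the body (one-sided upper 95% bounds 0.205 and 0.0721), against 1.03 and 0.813 for contigs beyond the spread between pools. The common shift of the spike-ins in the body, −0.59, bears on the balance of rises and falls and is not excluded. An effect of gossypol on the larvae stays as the hypothesis, and no batch at rearing, dissection or RNA extraction is named in the labels or was tested.

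The second pattern is the rest of body array of gossypol pool 4, which stood apart with a median of 2.56 for gut contigs, against −0.54 to −0.23 on the other 3. A scaling of the whole array is argued against, since its median of body contigs, 7.87, lies within the range of its group. Gut tissue carried into the sample stays open: of 390 gut contigs 90.5% were raised, at a median of 2.73% of their gut level, but the interquartile range of log2(excess over gut level) was 2.05, between the limits of 2 for and 4 against a nearly constant share that were set beforehand. The excess rose with the gut level (Spearman rho 0.748 across contigs), and the slope on the gut level was 1.14 on this array against 0.778 to 0.830 on the other 3, which goes with carry-over without deciding it. The gossypol diet alone is argued against as what set this array apart, since the other 3 gossypol bodies had the same diet. With the same gut contigs on all arrays they reached 1.19 and 0.90 for the sets from control pools 1 and 2 and 3 and 4. The control bodies reached 1.06 and 1.39, and the array of pool 4 lay at 3.32 and 3.28. The highest of the other 3 thus exceeded the higher of the 2 control bodies by 0.13 in the first set and stayed below it in the second. The lower control body was at 0.08 and −0.97 in these sets, below all of the other 3 (0.70 to 1.19 and 0.46 to 0.90). A smaller effect of the diet on gut contigs in the body stays open.

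The third pattern is that gut and body arrays of one pool deviated together (r between 0.209 and 0.424). The position on the slide or the order of handling is argued against by a median r of 0.0129 between same-numbered arrays of different diets. Carry-over of tissue between the samples is argued against by a median r of 0.416 among contigs with under 2-fold tissue difference, against 0.363 over all. Whether pools lay at different points along the gossypol response stays open. The largest absolute r of a pool's deviation with the gossypol change in the other tissue was 0.107. However, the changes of the 2 tissues themselves correlated at only 0.422. Even a pool displaced wholly along its own tissue's response would give an r near that, so the test could not decide. Differences between larvae of different pools, or handling shared by a pool, may remain and could not be tested further than this.

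The median of the body contigs on gut gossypol array 2 was 0.38, against 0.96 to 1.02 on the other 3. HVI-Contig11010 was at 5.31 on gut control array 1, against 8.11 to 8.64. HVI-RE-Contig_13999 was at −2.30 on gut control array 3, against 5.50 to 6.58. HVI-Contig13333 was at −4.31 on gut gossypol array 4, where no gossypol gut measured it above background, and at 6.12 on body control array 3, against 8.95 to 9.44. On body control array 3 HVI-Contig15846 was at −3.41, against 2.73 to 3.30, and HVI_Comb-contig69021 at 2.28, against 1.28 to 1.35.

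The gossypol response differed between gut and body in 16231 contigs by the test of the difference itself. In other splits of the pools' gut minus body differences (20292 contigs in the real split, 1 of 35), at most 2 contigs were called. Among named contigs the gut response minus the body response was −4.99 for HVI-RE-Contig_1304 (adjusted p = 0.0278), −4.93 for HVI-Contig21425 (0.0309), 3.95 for HVI-Contig11199 (0.00141), 4.99 for HVI_Comb-contig69021 (0.00168), 4.77 for HVI-Contig18935 (9.85e-05), −10.03 for HVI-RE-Contig_24762 (2.90e-04) and −6.12 for HVI-RE-Contig_13999 (0.0313). The 5793 contigs shared by both tissues were also reached by the real split alone (1 of 35 splits, at most 2 in any other). Other splits called at most 5 contigs in the gut and 19 in the body. Their shared counts were low for that reason and say nothing about sharing between lists of the real size. For the tissue differences the real split alone reached 32884 on control diet (1 of 35, at most 152) and 35405 on gossypol diet (1 of 35, at most 26). These 35 splits ignore the pairing of gut and body. Among the 8 splits that part all 4 gut and body pairs, the highest other counts were 0 and 1. With the pairing kept, 8 splits are too few to exclude chance.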

How the results depend on the processing

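The normexp on median signals, the pool blocks, the single name series, the gut contigs chosen on 2 control pools and the fit without control pool 1 were chosen after seeing the data. Under the alternatives 143 counts stayed within 1.5 times the reported ones and 6 moved further. This compares the sizes of lists and not their members. Requiring 2-fold left 13967 contigs in the gut, 7073 in the body and 2318 shared by both, and an adjusted p under 0.01 left 7624 in the body and 8771 for the difference between tissues, both by construction. Spike-in scaling gave 10637 for that difference; the cause was not tested. That scaling also moved the balance of rises and falls, as given with each count, by over 10 points except for the gut response and the control diet tissues. Of its 15189 body calls only 7173 were among the 14538 reported ones, while 18417 of its 18949 gut calls were also reported. Without one array the counts ran from 20776 to 23209 in the gut, 10189 to 12879 in the body, 28974 to 30724 and 30616 to 32352 between tissues on control and gossypol diet, 13897 to 16172 for the difference and 4128 to 5903 shared. Replicate number as a block gave 25354 and 15111 contigs in gut and body. Pool as a replicate block gave 35333, 38005 and 20292 for the tissue comparisons and the difference, and no block changed a call of a named contig. Of 20 named values, 19 kept direction and call under every alternative run, and HVI-RE-Contig_13999 lost its call in 10 of 30, one of them the stricter threshold, with adjusted p from 4.70e-07 to 0.0800. The named contigs were chosen on these same arrays for the largest called differences, so keeping direction and call is no independent support. Folds moved more: normexp made differences smaller, to 8.89 for HVI-Contig18598, 9.19 for HVI_Comb-contig76256, −8.75 for HVI-Contig24127, −8.79 for HVI-RE-Contig_443, 9.30 for HVI-Contig11010, 8.81 for HVI-Contig15846, −8.38 for HVI-Contig5103, −8.03 for HVI-Contig13333, −6.23 for HVI-RE-Contig_1304 and −5.15 for HVI-RE-Contig_13999. In the body spike-in scaling gave 8.59 for HVI-Contig3376, 8.57 for HVI-Contig19119, −8.24 for HVI-Contig13333 and −4.39 for HVI-Contig11199. Array weights gave 7.07 for HVI-RE-Contig_10636, −8.76 for HVI-Contig24127 and −8.75 for HVI-RE-Contig_443. The normexp on mean signals, slide as a block, gene lists and the deposited value table between tissues were not run. Signal over background limits the dim contigs: those well above background on under 4 arrays entered only the alternative with no such filter, which tested 80237 contigs and called 28072 in the gut and 16642 in the body.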

Other observations

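The test of tissue-enriched contigs was set before its result was seen. Contigs enriched at least 4-fold in the gut over the body were taken from 2 control pools, and their gossypol change was measured against the other 2 control pools. With the set from pools 1 and 2, 5561 gut-enriched contigs had a median log2 change of −0.39 in the gut, against 0.10 for the 46725 others tested. With the set from pools 3 and 4, 5411 contigs were at −0.18, against 0.12 for the others. At least 2-fold lower with gossypol were 31.2% and 26.1% of the gut-enriched contigs, against 12.4% and 12.7% of the others. Others weighted to the same brightness had a median of 3.98e-04 and 0.04. At least 2-fold higher were 14.5% and 19.4% of the gut-enriched contigs, against 16.1% and 16.0%.

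The same was asked of body-enriched contigs in the rest of the body. With the set from pools 1 and 2, 7053 contigs had a median change of −0.08, against −0.09 for the others, and with the set from pools 3 and 4, 7511 contigs were at −0.05 against −0.08. At least 2-fold lower were 20.1% and 18.1%, against 7.03% and 7.16% of the others, and at least 2-fold higher 12.02% and 15.36%, against 7.993% and 8.9997%.

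One hypothesis was that gossypol lowers gut-enriched transcripts in the gut. The median of the gut-enriched contigs lay below that of the others by more than the 0.2 set beforehand with both sets of control pools (differences −0.49 and −0.30). This is consistent with the hypothesis. The corresponding hypothesis for body-enriched transcripts in the rest of the body was negative. Their median lay 0.01 and 0.0371 above that of the others, although larger shares of them were at least 2-fold lower and at least 2-fold higher.

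Some named contigs had close differences, as seen after the fits. HVI-RE-Contig_10636, HVI-Contig3376 and HVI-Contig19119 rose by 7.70, 7.63 and 7.63 in the gut and by 7.31, 8.00 and 7.98 in the body. HVI-RE-Contig_1304 and HVI-Contig21425 had −6.87 and −6.84 in the gut, and HVI-Contig24127 and HVI-RE-Contig_443 had −9.60 and −9.55 between tissues on control diet. Whether these names stand for shared transcripts was not tested, since no sequences were used here.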
